A study of Rattus norvegicus with 10 samples.

How the data were processed

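RNA was sequenced from neonatal rat cardiomyocytes that overexpressed YAP5SA or YAP5SA-S94A. Of the 10 samples of the series, the 4 RNA-seq libraries, 2 per form, were analysed. The 6 CUT&RUN samples were not analysed here. The labels call the libraries biological replicates and do not say whether they came from separate cultures or isolations. Per the labels, libraries were directional, from poly(A) RNA. The processing notes name fastp, HISAT2 2.2.1, StringTie 2.2.1 and R 4.3.1 with a count-based test that was not used here, and the rat build rn7, with no settings.

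Each deposited table held 40903 entries with 3 measures. The TPM values, transcripts scaled to the same sum in every library, were computed by the authors. The FPKM values, also computed by the authors, were a fixed multiple of TPM within each library. The Coverage column, per the file headers, gave the per-base read coverage of each gene and was not scaled for depth. Read counts per gene were not used here. The highest ratio of coverage to FPKM in a table, shared by more than 3199 entries in 3 libraries and by 3199 in the other, gave the aligned sequence as 5.10 and 4.02 gigabases for YAP5SA replicates 1 and 2 and 5.02 and 4.97 gigabases for YAP5SA-S94A replicates 1 and 2. The 10 most abundant entries took 8.72% and 10.6% of TPM in YAP5SA and 12.1% and 12.97% in YAP5SA-S94A.

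Entries that shared a gene name were summed, which gave 39784 names, 517 of them on more than 1 entry. Of these names 35027 were found in a gene table of a later rat build, 99.8% of them on the same chromosome, and the printed coordinates are those of the deposited tables. Whether counting used the strand was not stated, so genes that overlap an expressed gene on the opposite strand are uncertain, among them Mns1, Dusp13a, Atp6ap1l, Cxcl11, Cxcl10, Tead2, Kif20a, Rbl2, Pfkm, Cryab, Ddit3 and ND6. ATP6 overlaps its neighbours on the same strand. Reads of close paralogs (tubulins, myosin heavy chains, ribosomal protein genes) cannot be divided with certainty.

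Genes with a mean TPM of at least 1 over the 4 libraries (13420) were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, using moderated t statistics with an intensity trend (2 residual and 5.09 prior degrees of freedom). P values were adjusted by the Benjamini-Hochberg method and called under 0.05. The only comparison was YAP5SA minus YAP5SA-S94A. The 37 gene lists were fixed before the data were examined, and the 35 with at least 5 tested genes (877 genes in all) were tested with camera at a preset correlation of 0.01, with adjusted p over the lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera reads its statistic on the 2 residual degrees of freedom of the design. With a preset correlation the degrees of freedom follow the number of genes. Adjusted p values with an estimated correlation are therefore large by construction. They do not show that correlation among genes undoes a list call. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

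The genes named in the report follow a rule set before the data were examined: the 10 largest increases and the 10 largest decreases among called genes with a symbol whose groups did not overlap; Yap1, Wwtr1, Tead1 to Tead4, Ccn1, Ccn2, Ankrd1, Amotl2, Axl and Lats2; and for each list up to 4 called members with the smallest p, or up to 2 members given as values where none was called. One gene that the rule names is not reported here. Genes outside this rule are given as chosen after their values were seen.

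The method was checked on simulated data with 200 changed genes among 13420. It recovered 56% of genes with a log2 change of 1 and 85% of those with a change of 2. There were 5 false calls among 146, and 0 of 30 random lists were called. The changed genes were drawn from the more highly expressed ones, so recovery of low genes was not measured. Values were drawn independently for each gene, so the random lists do not test calls of lists whose genes vary together. The simulated share of changed genes was also far below the share called in the data. The alternatives tried were other pseudocounts, filters, units, scalings, variance models and thresholds, the replicate number as a block, and each library left out in turn.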

Results

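Gene expression was measured by RNA sequencing in neonatal rat cardiomyocytes, the contractile muscle cells of the newborn rat heart, that overexpressed either of 2 forms of YAP. YAP is a transcriptional coactivator that the Hippo pathway restrains and that binds DNA through TEAD transcription factors. YAP5SA is an activated form whose inhibitory phosphorylation sites are changed from serine to alanine. YAP5SA-S94A carries a further serine-to-alanine change that disrupts binding to TEAD. The RNA-seq part held 4 libraries, 2 per form, and the deposited tables corresponded to 5.10 and 4.02 gigabases of aligned sequence in the YAP5SA libraries and 5.02 and 4.97 gigabases in the YAP5SA-S94A libraries. The 6 CUT&RUN samples of the series were not analysed here. With no RNA-seq library of uninfected or GFP cells among those used, each difference is one between the 2 YAP forms and does not show which of them departed from the untreated state. The comparison addresses which expression changes of activated YAP go with its ability to bind TEAD, in a study concerned with microtubules and sarcomere disassembly. Gene values are TPM (transcripts scaled to a fixed sum per library), given as mean ± SD with n = 2 per group. Fold changes are YAP5SA minus YAP5SA-S94A on the log2(TPM + 1) scale, which understates the change of low genes. A gene is described as called, or as having risen or fallen, when its limma adjusted p lay under 0.05.

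The largest differences included the myosin heavy chain genes Myh3 and Myh8 and the keratin gene Krt18, higher in YAP5SA, and the potassium channel subunit gene Kcnip2 and the nuclear receptor gene Rxrg, lower in YAP5SA. Myh3, the embryonic myosin heavy chain (chromosome 10, 51770177 to 51793994, rn7), stood at 185 ± 37.0 TPM against 0.846 ± 0.015 (log2 fold change 6.64, SE 0.17, limma adjusted p = 1.08e-05). Myh8, the perinatal myosin heavy chain, reached 48.5 ± 4.16 TPM against 0.053 ± 0.021, and the epithelial keratin gene Krt18 133 ± 8.87 against 5.02 ± 2.01. In the other direction, Kcnip2, which encodes a subunit of the transient outward potassium channel (chromosome 1, 244641147 to 244664939), fell from 49.5 ± 0.018 TPM in YAP5SA-S94A to 2.07 ± 0.089 in YAP5SA (log2 fold change −4.04, SE 0.15, limma adjusted p = 1.81e-05). Rxrg, the retinoid X receptor gamma gene, fell by 3.33 on the log2 scale, from 52.0 ± 4.04 to 4.27 ± 0.39 TPM.

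In total 4420 of 13420 tested genes (32.9%) differed between the forms, 2337 higher and 2083 lower in YAP5SA. The larger count was that of the lower genes with quantile normalization (2230 higher, 2443 lower), with the mitochondrial chromosome left out (2134 and 2660), with FPKM (1868 and 1875) and without YAP5SA replicate 1 (2376 and 2739). Among them 1005 rose and 610 fell by at least 1 on the log2 scale. Besides Myh3, Myh8 and Krt18, the 10 largest increases among genes with a symbol were in Lce1m (log2 fold change 5.72), Mns1 (5.22), Cd2 (4.96), Neto2 (4.86), Marchf11 (4.76), Tnfsf18 (4.54) and Rassf7 (4.36). Cd2, a surface antigen of T cells, stood at 30.0 and 30.2 TPM in the YAP5SA libraries and was listed at 0 in both YAP5SA-S94A libraries. Tnfsf18, a ligand of the tumour necrosis factor family, was the most abundant of the 10 after the change, at 376 ± 81.2 against 15.1 ± 2.89 TPM. The 10 largest decreases were, besides Kcnip2 and Rxrg, in Trim50 (−3.85), Cxcl11 (−3.64), Reg3b (−3.47), Rab3b (−3.44), Atp6ap1l (−3.44), Gabrb2 (−3.25), Dusp13a (−3.20) and Doc2g (−3.16). Reg3b, a secreted C-type lectin, fell from 543 ± 1.79 to 48.6 ± 9.53 TPM, and Dusp13a, listed at 0 in both YAP5SA libraries, stood at 6.95 and 9.56 TPM in the others. Values of Mns1, Dusp13a, Cxcl11 and Atp6ap1l are uncertain, because each overlaps an expressed gene on the opposite strand and the use of strand in counting was not given in the sources used here. Cxcl11 lies within the span of Art3, which itself fell by 1.47 on the log2 scale, and Atp6ap1l overlaps the ribosomal gene Rps23, at 1655 TPM over the 4 libraries. The log2 fold change was 0.195 for Rps23, 0.12 for Tex9, which overlaps Mns1, and −0.177 for Samd8, which overlaps Dusp13a. These changes were far smaller than those of the genes they overlap.

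The difference between the groups exceeded the spread within them. Across genes, log2 values correlated at r = 0.985 within YAP5SA and 0.991 within YAP5SA-S94A, against 0.926 to 0.932 between the forms, with genes not counting as independent replicates. The groups did not overlap in 9158 of the tested genes, where chance would give 33.3%, and in each of the 4420 called genes. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so the calls rest on the spread that limma pools over genes. Without YAP5SA-S94A replicate 1 the number of genes called lower was 1312, and without YAP5SA-S94A replicate 2 it was 1314.

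**Figure D1:**
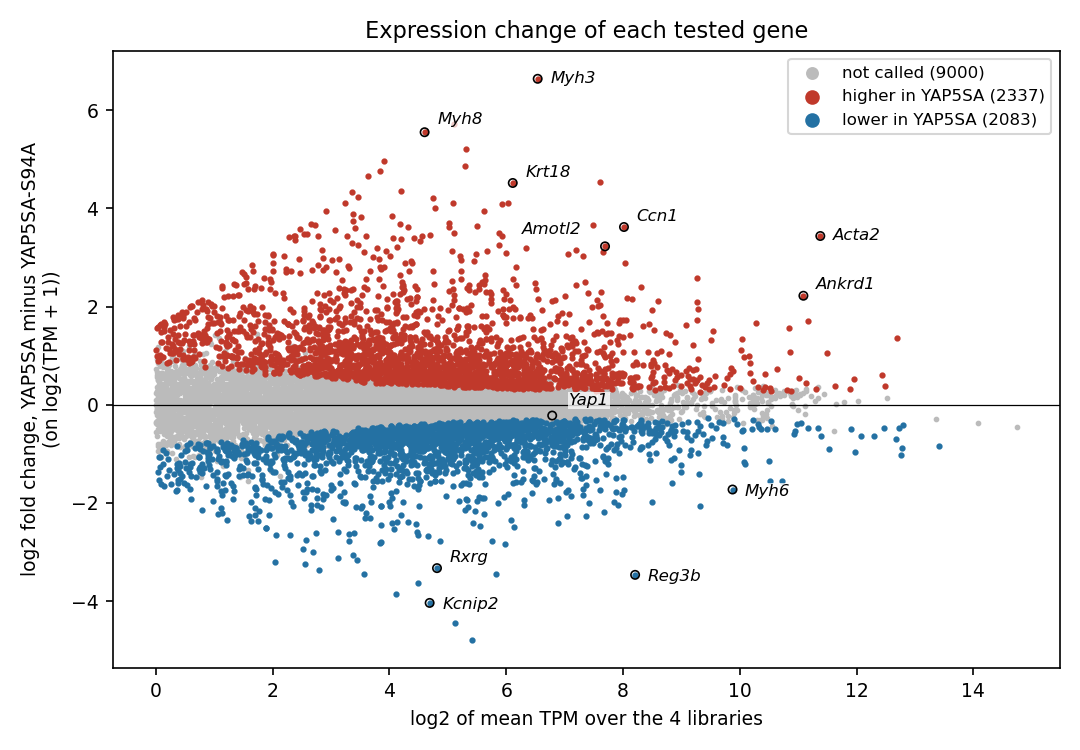
Log2 fold change (YAP5SA minus YAP5SA-S94A, on log2(TPM + 1)) of each tested gene against the log2 of its mean TPM over the 4 libraries, with genes called higher in red, called lower in blue and the others in grey. The 2337 higher and 2083 lower genes span the expression range, with Myh3 at 6.64 the highest and Yap1 at −0.22 among the genes not called.

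Established YAP/TEAD target genes were higher in the form that binds TEAD. Ccn1, a secreted matricellular protein gene (chromosome 2, 234562410 to 234565370), stood at 480 ± 58.9 TPM, 12.6-fold its level in YAP5SA-S94A (log2 fold change 3.62, SE 0.12, limma adjusted p = 1.39e-05). Its relative Ccn2 (chromosome 1, 20802199 to 20805315) stood at 995 ± 37.5 against 256 ± 10.5 TPM, and Ankrd1, a stress-responsive ankyrin repeat protein of the sarcomere (chromosome 1, 233815851 to 233834891), at 3592 ± 467 against 766 ± 1.44 TPM. Amotl2, which encodes a junctional protein that sequesters YAP (chromosome 8, 103303368 to 103319161), rose by 3.23 on the log2 scale to 375 ± 44.3 TPM. The receptor tyrosine kinase gene Axl rose by 0.51 (limma adjusted p = 0.0128), a call lost without YAP5SA-S94A replicate 1 (adjusted p = 0.111). Of 21 tested members of the YAP/TEAD target list 14 rose and 1 fell, and the counts were 14 and 1 when adjusted over the list alone; without YAP5SA replicate 2 the number that fell was 2. The list's median log2 fold change was 0.77 (camera adjusted p = 7.12e-07 with a preset correlation and 0.267 with an estimated correlation). Here and for the other lists, camera with an estimated correlation rests on 2 residual degrees of freedom, so its p could hardly be small.

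The transcripts of YAP, TAZ and the TEAD factors differed from one another in direction and in whether they were called. Yap1 stood at 102 ± 4.13 TPM in YAP5SA and 119 ± 3.42 in YAP5SA-S94A (chromosome 8, 5095705 to 5166808; log2 fold change −0.22, SE 0.10, limma adjusted p = 0.122), a difference not called. It was called lower without YAP5SA replicate 1 (limma adjusted p = 0.0473) and with the mitochondrial chromosome left out (adjusted p = 0.0494). How much of the transgene this row captures is unknown, because the labels give neither its species nor its sequence. Wwtr1, which encodes the YAP paralog TAZ, stood at 70.7 against 68.6 TPM (limma adjusted p = 0.943), and the sign of its difference changed without YAP5SA replicate 1 (log2 fold change −0.26) and without YAP5SA-S94A replicate 2 (−0.14). Among the TEAD genes, Tead1 rose from 81.9 ± 3.70 to 158 ± 5.49 TPM (log2 fold change 0.94, limma adjusted p = 4.89e-04) and Tead4 from 1.97 ± 0.38 to 16.2 ± 2.10 (2.54, limma adjusted p = 1.38e-04). Tead2 fell by 0.41 (limma adjusted p = 0.0451), a call lost with FPKM (adjusted p = 0.0593), without an intensity trend (0.0739) and with no filter (0.0784). The call was also lost without each of 3 libraries. There the log2 fold change was −0.32 without YAP5SA replicate 2, −0.37 without YAP5SA-S94A replicate 1 and −0.45 without YAP5SA-S94A replicate 2. Tead3, at 50.4 ± 14.2 against 73.0 ± 5.93 TPM, was not called (limma adjusted p = 0.0605), but it was called lower in 6 other settings: without YAP5SA replicate 1 (adjusted p = 0.00647), without YAP5SA-S94A replicate 2 (0.0247), with median-of-ratios scaling (0.032), with quantile normalization (0.0393), with the mitochondrial chromosome left out (0.0249) and with the replicate numbers as a block (0.00259).

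Genes of the Hippo pathway, which phosphorylates and restrains YAP, also differed. Lats2, a YAP kinase, stood at 108 ± 5.93 against 30.9 ± 1.09 TPM (log2 fold change 1.77, limma adjusted p = 5.17e-05). Amot, the angiomotin gene, rose by 3.46 on the log2 scale and the scaffold gene Wwc2 by 1.81. Of 26 tested Hippo components 12 rose and 2 fell (13 and 4 when adjusted over the list alone), with a median log2 fold change of 0.23. The 26 include Yap1, Wwtr1 and Tead1 to Tead4, and also Lats2 and Amotl2 of the YAP/TEAD target list. These counts are thus not separate from the results above. The Hippo list passed camera (adjusted p = 0.00256), with adjusted p = 0.36 with an estimated correlation. Its count of genes that fell was 4 without YAP5SA replicate 1, 0 without YAP5SA-S94A replicate 1 and 1 without YAP5SA-S94A replicate 2, where the median was 0.34.

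**Figure D2:**
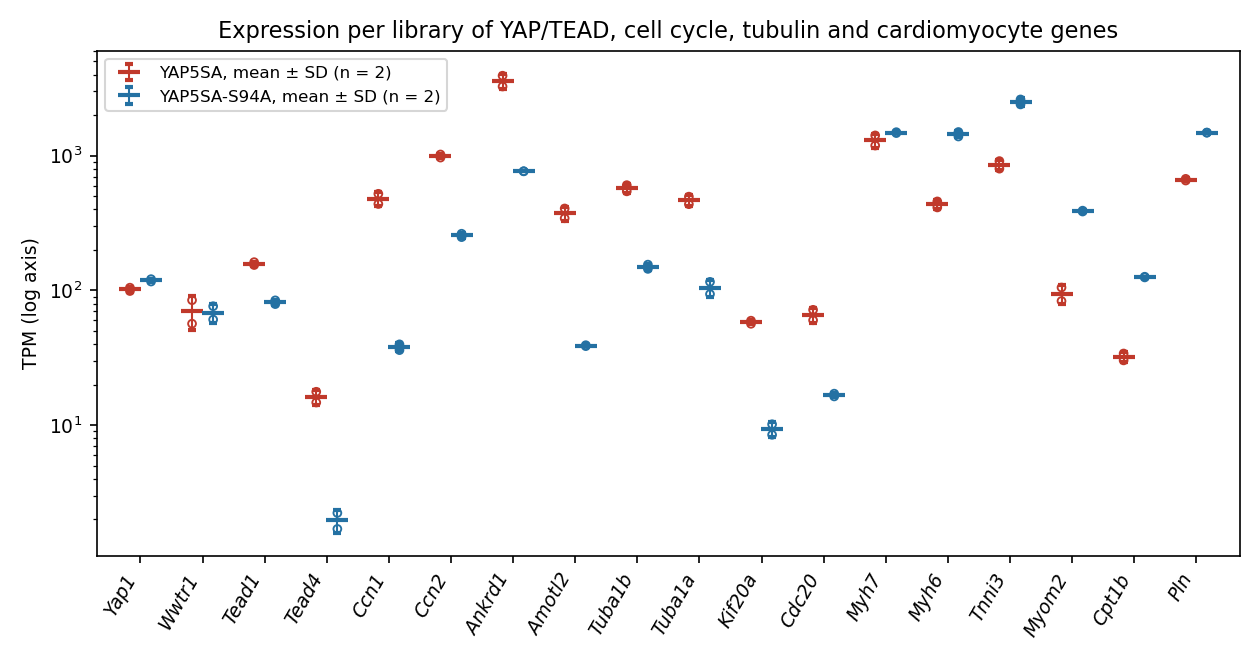
TPM on a log axis of YAP/TEAD pathway, tubulin, cell cycle and cardiomyocyte genes, with open circles for the 4 libraries and bars for mean ± SD (n = 2 per form, YAP5SA in red and YAP5SA-S94A in blue). Ccn1 had a log2 fold change of 3.62 and Myh6 stood at 436 against 1444 TPM, while Yap1, Wwtr1 and Myh7 were not called.

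Genes of cell division were higher in YAP5SA as a group. Kif20a, a kinesin of cytokinesis, stood at 58.2 ± 2.18 against 9.34 ± 1.18 TPM (log2 fold change 2.52, limma adjusted p = 4.04e-05). Cdc20, an activator of the anaphase-promoting complex, rose by 1.91 on the log2 scale, the contractile ring gene Anln by 2.38 and the spindle midzone gene Prc1 by 1.59. Of 58 tested genes of the G2/M and cytokinesis list 53 rose and 0 fell (54 and 0 when adjusted over the list alone). The median log2 fold change was 1.31 (camera adjusted p = 1.86e-19; adjusted p = 0.223 with an estimated correlation). In the S phase list 25 of 43 tested genes rose and 0 fell (26 and 0 when adjusted over the list alone), with a median of 0.67 (camera adjusted p = 2.03e-07; adjusted p = 0.223 with an estimated correlation). Its leading members were Rrm2, a subunit of ribonucleotide reductase (73.6 ± 2.12 against 14.3 ± 1.54 TPM), cyclin D1 (Ccnd1, log2 fold change 1.23), thymidine kinase (Tk1, 1.65) and Cdk6 (1.56). In the same libraries 6 of 26 fibroblast and matrix genes and 5 of 10 epicardial and mesothelial genes rose.

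Inhibitors of the cell cycle moved both ways. Cdkn2b, a cyclin-dependent kinase inhibitor, rose by 0.85 on the log2 scale and the antiproliferative gene Btg2 by 0.84. Cdkn1b, which encodes the inhibitor p27, fell by 0.88, and the retinoblastoma-family gene Rbl2 by 0.64 (limma adjusted p = 0.0141), a call lost without YAP5SA-S94A replicate 1 (adjusted p = 0.0747) or 2 (adjusted p = 0.13). Of 14 tested inhibitors 3 rose and 4 fell, also when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.914). Its median log2 fold change was 0.05 while camera's direction was down; the median was −0.057 without YAP5SA-S94A replicate 2 and also below 0 without YAP5SA replicate 1, and 2 fell without either YAP5SA-S94A library.

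Most tubulin genes were higher in YAP5SA. The list holds the alpha and beta tubulins, the subunits of microtubules, and also gamma, delta and epsilon tubulins. Tuba1b stood at 574 ± 42.9 against 150 ± 7.71 TPM (chromosome 7, 130090663 to 130093644; log2 fold change 1.93, SE 0.10, limma adjusted p = 3.06e-05) and Tuba1a at 467 ± 42.5 against 105 ± 15.5. The beta-tubulin genes Tubb4b and Tubb6 rose by 1.46 and 1.76 on the log2 scale. Of 15 tested tubulin genes 10 rose and 1 fell, also when adjusted over the list alone. The exception was Tuba8 (log2 fold change −1.65), named after its value was seen. The median was 0.89 (camera adjusted p = 8.92e-05; adjusted p = 0.36 with an estimated correlation). Some tubulin genes are near-identical in sequence, so the split of reads among those is uncertain. Together the listed genes took 0.238% and 0.225% of TPM in the YAP5SA libraries against 0.1001% and 0.0932% in the others.

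Genes that act on microtubules moved both ways, without a list call. Hdac6, a tubulin deacetylase, rose from 23.0 ± 1.28 to 71.8 ± 6.02 TPM (log2 fold change 1.60, limma adjusted p = 1.20e-04). Tacc3, which stabilizes spindle microtubules, rose by 1.80, the tip-tracking gene Gtse1 by 1.09, and the tubulin tyrosine ligase gene Ttl by 1.00. Of 47 tested genes for microtubule growth and microtubule-associated proteins 14 rose and 9 fell (15 and 10 when adjusted over the list alone), with a median of 0.07 and no list call (camera adjusted p = 0.28). The median was −0.014 without YAP5SA replicate 1 and 0.21 without YAP5SA replicate 2. Among those that fell was Map4, the ubiquitous microtubule-associated protein, at 145 ± 1.19 against 224 ± 0.44 TPM, named after its values were seen. The count that fell was 3 without YAP5SA-S94A replicate 1 and 4 without replicate 2. Of 31 tested kinesin and dynein motor genes 5 rose and 8 fell (6 and 9 when adjusted over the list alone; camera adjusted p = 0.994), the latter count being 3 without either YAP5SA-S94A library. Kif5b, the ubiquitous kinesin heavy chain, stood at 315 ± 42.9 against 113 ± 5.69 TPM, and the dynein genes Dynll1 and Dync1i1 rose by 1.05 and 2.06. The kinesin light chain gene Klc4 fell by 1.36. The motor list's median of 0.04 was positive and camera's direction down, with medians of 0.022 and 0.019 without YAP5SA replicates 1 and 2 and 0.015 and 0.059 without YAP5SA-S94A replicates 1 and 2.

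**Figure D3:**
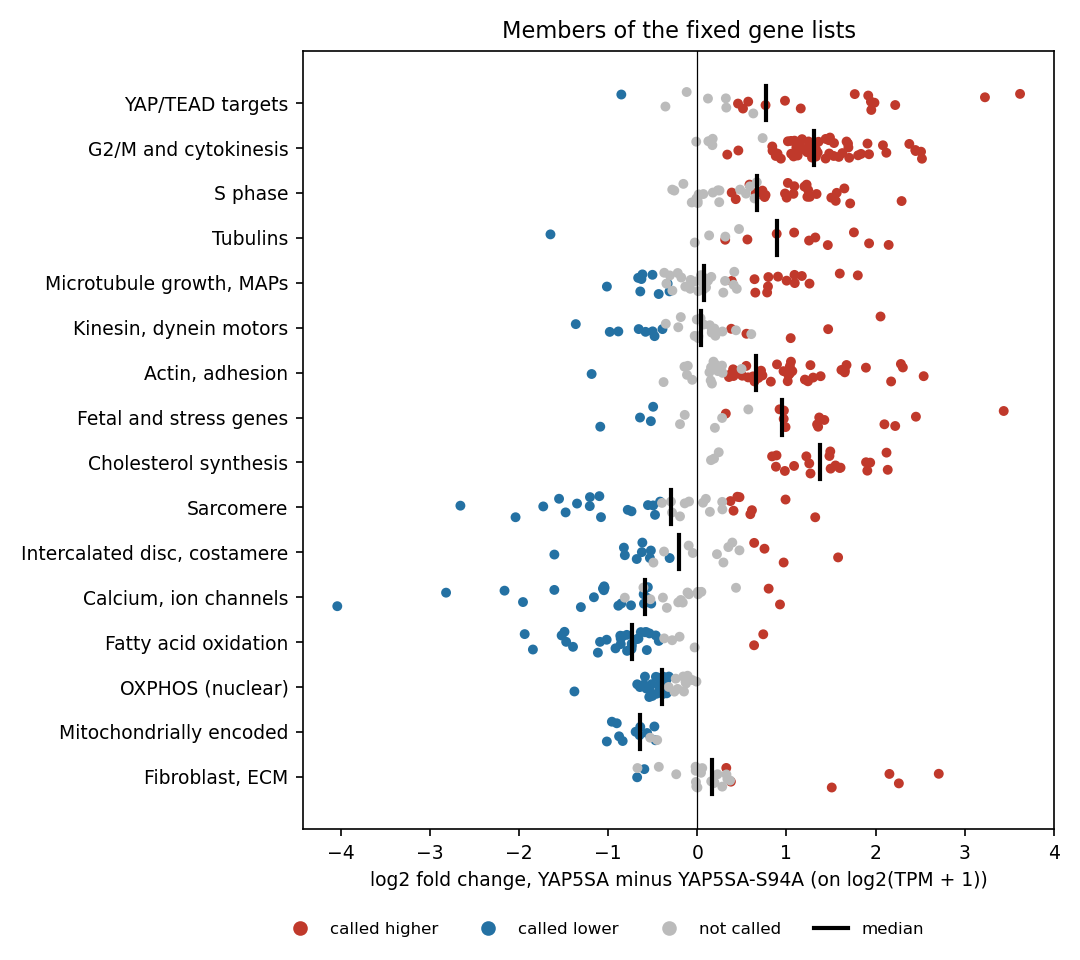
Log2 fold change (YAP5SA minus YAP5SA-S94A, on log2(TPM + 1)) of each tested member of 16 gene lists, with red and blue points for genes called higher and lower, grey points for the others and black bars for the list medians. The lowest median was that of fatty acid oxidation (−0.74) and the highest that of cholesterol synthesis (2.60-fold), and sarcomere and microtubule-associated genes lay on both sides of 0.

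Sarcomere genes, which encode the contractile unit of heart muscle, moved both ways with more falling than rising. Myh6, the alpha myosin heavy chain of the adult rat heart (chromosome 15, 28418120 to 28442316), fell from 1444 ± 78.4 to 436 ± 31.7 TPM (log2 fold change −1.73, SE 0.10, limma adjusted p = 4.15e-05). Tnni3, cardiac troponin I, fell from 2508 ± 151 to 857 ± 78.4 TPM, the M-band gene Myom2 by 2.04 on the log2 scale and Cmya5 by 2.66. Of 35 tested sarcomere genes 16 fell and 8 rose (19 and 10 when adjusted over the list alone), with a median of −0.29. The list passed camera (adjusted p = 0.0101), with adjusted p = 0.36 with an estimated correlation, and its call was lost under quantile normalization (adjusted p = 0.0634) and without YAP5SA replicate 1 (adjusted p = 0.0696). The genes that rose, named after their values were seen, included cardiac actin Actc1 (6698 ± 111 against 4434 ± 231 TPM), Synpo2l (log2 fold change 1.32), Xirp1 (0.99) and Csrp3 (0.61). Their number was 5 without YAP5SA-S94A replicate 1 and 3 without replicate 2. Myh7, the beta myosin heavy chain, also named after its values were seen, stood at 1302 ± 159 against 1483 ± 16.4 TPM and was not called (limma adjusted p = 0.207).

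Genes of the intercalated disc and costamere, which couple cardiomyocytes to each other and to the matrix, split as well. The desmosomal gene Dsp fell by 1.60 on the log2 scale, from 183 ± 4.55 to 59.7 ± 1.69 TPM, and Gja1, the connexin of the ventricular gap junction, by 0.82. Dtna, the alpha-dystrobrevin gene, rose by 1.58 and vinculin (Vcl) by 0.75. Of 22 tested genes 4 rose and 9 fell (5 and 10 when adjusted over the list alone), without a list call (camera adjusted p = 0.309).

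More fetal and stress-associated cardiac genes rose than fell. Acta2, smooth muscle actin, stood at 4877 ± 70.7 against 449 TPM (log2 fold change 3.44, SE 0.09, limma adjusted p = 1.08e-05), and Tagln, a smooth muscle actin-binding protein gene, rose by 1.34. The skeletal-type myosin-binding protein gene Mybpc2 rose by 2.45. Sarcomere genes of this list that did not rise included Myh7 (−0.19, not called) and Tnni1 (−0.49), both named after their values were seen. Of 22 tested genes 13 rose and 4 fell, also when adjusted over the list alone, with a median of 0.95 (camera adjusted p = 3.59e-04; adjusted p = 0.36 with an estimated correlation). Acta2 and Tagln are also in the smooth muscle and pericyte list. Its genes took 0.721% and 0.694% of TPM in the YAP5SA libraries and 0.164% and 0.162% in the others. Most of that share, and of the difference, came from Acta2 and from Tagln, which stood at 1509 ± 55.3 against 593 ± 5.37 TPM. The smooth muscle and pericyte list was not called (camera adjusted p = 0.123). Cardiac transcription factor genes fell in 9 of 21 cases and rose in 1, also when adjusted over the list alone (median −0.25; camera adjusted p = 0.00572; adjusted p = 0.559 with an estimated correlation). The homeodomain gene Hopx fell by 1.58 on the log2 scale, the T-box gene Tbx5 by 1.49, the retinoid receptor gene Rxra by 1.29 and the estrogen-related receptor gene Esrrg by 1.11. Among 30 tested genes of sarcomere protein turnover 3 rose and 12 fell (3 and 16 when adjusted over the list alone; median −0.30; camera adjusted p = 1.74e-04; adjusted p = 0.507 with an estimated correlation). The muscle ubiquitin ligase genes Trim63 and Fbxo32 fell by 1.46 and 2.28, and the autophagy receptor gene Sqstm1 by 1.40. Cryab, a small heat shock protein gene, rose by 1.70 to 3537 ± 106 TPM, a value that is uncertain because Hspb2 overlaps it on the opposite strand. The count of turnover genes that fell was 19 without YAP5SA replicate 1, and that of those that rose was 5 without YAP5SA replicate 2 and 1 without YAP5SA-S94A replicate 1. The median of the transcription factor genes was −0.71 without YAP5SA replicate 1 and −0.44 without YAP5SA-S94A replicate 2. The count of these genes that rose was 2 without YAP5SA replicate 2 and 0 without either YAP5SA-S94A library.

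Genes of calcium handling and ion channels were lower in YAP5SA. Pln, which encodes phospholamban, the inhibitor of the sarcoplasmic reticulum calcium pump, fell from 1483 ± 3.60 to 664 ± 13.6 TPM (log2 fold change −1.16, limma adjusted p = 9.78e-05), and the calcium-binding protein gene Hrc fell by 1.60. Calsequestrin (Casq2) rose by 0.93. Of 36 tested genes 20 fell and 2 rose (23 and 2 when adjusted over the list alone), with a median of −0.58 (camera adjusted p = 2.85e-06; adjusted p = 0.36 with an estimated correlation).

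Mitochondrial energy metabolism was lower at the transcript level. Cpt1b, the muscle enzyme of fatty acid entry into mitochondria, fell from 126 ± 1.05 to 32.2 ± 2.68 TPM (log2 fold change −1.94, limma adjusted p = 4.21e-05), Acsl1 by 1.84, Hadh by 1.52 and Cpt1a by 1.39. Of 34 tested genes of fatty acid oxidation 28 fell and 2 rose (29 and 2 when adjusted over the list alone), with a median of −0.74 (camera adjusted p = 8.44e-11; adjusted p = 0.223 with an estimated correlation). Of 36 nuclear genes of oxidative phosphorylation 25 fell and 0 rose (29 and 0 when adjusted over the list alone), with a median of −0.39 (camera adjusted p = 5.9e-09; adjusted p = 0.223 with an estimated correlation). Cox8b, a heart-type subunit of cytochrome oxidase, fell from 741 ± 95.8 to 283 ± 17.2 TPM, and the ATP synthase genes Atp5pb, Atp5f1b and Atp5f1a fell by 0.67, 0.64 and 0.60. That count was 9 without YAP5SA-S94A replicate 1 and 11 without replicate 2. Of 13 mitochondrially encoded genes 11 fell, 13 when adjusted over the list alone (median −0.65; camera adjusted p = 5.68e-06; adjusted p = 0.507 with an estimated correlation). Among them ATP6 fell by 1.01, ND2 by 0.96, COX3 by 0.84 and ND6 by 0.56. With no filter on low values 3 of the 13 were called. The mitochondrial chromosome took 7.53% and 10.2% of TPM in the YAP5SA libraries and 12.6% and 14.03% in the YAP5SA-S94A libraries.

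Glycolysis genes divided evenly. The glucose transporter gene Slc2a3 rose from 10.4 ± 0.40 to 108 ± 0.18 TPM (log2 fold change 3.25, limma adjusted p = 1.62e-05), whereas the insulin-responsive transporter gene Slc2a4 fell by 1.82, the muscle enolase gene Eno3 by 1.73 and the muscle phosphofructokinase gene Pfkm by 1.53. Of 26 tested genes 8 rose and 8 fell (8 and 9 when adjusted over the list alone; camera adjusted p = 0.489), and 4 rose without YAP5SA-S94A replicate 2. Cholesterol synthesis genes rose together, 19 of 22 with 0 falling, also when adjusted over the list alone (median 2.60-fold; camera adjusted p = 1.06e-11; adjusted p = 0.223 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, stood at 155 ± 12.7 against 39.6 ± 1.45 TPM, and Msmo1 and Fdps rose by 2.12 and 1.60 on the log2 scale.

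The actin cytoskeleton and adhesion list rose broadly. Cdc42ep3, an effector of the small GTPase Cdc42, stood at 282 ± 2.80 against 57.1 ± 4.45 TPM (log2 fold change 2.28, limma adjusted p = 2.04e-05), Cnn3 rose by 2.18, the LIM-domain gene Ajuba by 2.31 and the non-muscle myosin light chain gene Myl12a by 1.66. Of 52 tested genes 36 rose and 1 fell (39 and 1 when adjusted over the list alone), with a median of 0.66 (camera adjusted p = 1.4e-12; adjusted p = 0.334 with an estimated correlation), and 3 fell without YAP5SA replicate 1. Immediate early genes and targets of serum response factor rose in 11 of 19 cases and fell in 1 (12 and 1 when adjusted over the list alone; median 0.68; camera adjusted p = 0.00124; adjusted p = 0.535 with an estimated correlation). Myc rose by 1.45 on the log2 scale, Klf2 by 1.44, Klf4 by 1.05 and Klf6 by 0.68, the count that rose was 7 without YAP5SA-S94A replicate 2, and 2 fell without YAP5SA replicate 1. Growth factor and insulin-like growth factor signalling genes rose in 13 of 37 cases and fell in 5, also when adjusted over the list alone, without a list call (camera adjusted p = 0.106). Hbegf, an epidermal growth factor receptor ligand, stood at 61.2 ± 13.3 against 6.02 ± 0.95 TPM, Bmp4 at 30.1 ± 5.27 against 10.9 ± 0.69, and Tgfb3 and Fgfr1 rose by 1.33 and 0.94. The number that fell was 3 without YAP5SA-S94A replicate 2.

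Among the stress and inflammatory lists, those of p53 signalling and NF-κB were called higher. Of 29 tested genes of p53 signalling and apoptosis 13 rose and 3 fell (13 and 4 when adjusted over the list alone; median 0.42; camera adjusted p = 0.0166; adjusted p = 0.491 with an estimated correlation). Gadd45g, a growth arrest and DNA damage gene, rose by 3.15 on the log2 scale and the death receptor gene Fas by 1.02, while Sesn1 fell by 1.25 and the pro-apoptotic gene Bcl2l11 by 1.15. The count that rose was 7 without either YAP5SA-S94A library, and the median was 0.24 without YAP5SA replicate 1. In the inflammatory NF-κB list 7 of 17 genes rose and 1 fell (8 and 1 when adjusted over the list alone; median 0.45; camera adjusted p = 0.0196; adjusted p = 0.507 with an estimated correlation). The chemokine gene Ccl20 rose by 3.43, Ptgs2 by 3.22, Vcam1 by 2.10 and Icam1 by 1.77. The list call was lost without YAP5SA replicate 1 (camera adjusted p = 0.0875) and without YAP5SA replicate 2 (adjusted p = 0.0676), and 3 of its genes fell without YAP5SA replicate 1. Its median was 0.26 without YAP5SA replicate 1 and 0.19 without YAP5SA-S94A replicate 1. Interferon response genes rose in 1 of 21 cases (Tap1, log2 fold change 0.68) and fell in 4 (1 and 3 when adjusted over the list alone; camera adjusted p = 0.106), with Usp18 at −1.43, Ifi27 at −0.31 and Cxcl10, which overlaps Art3, at −1.99. The limma call of Usp18 was lost without YAP5SA replicate 1 (adjusted p = 0.0579) or 2 (0.0654), that of Ifi27 without YAP5SA-S94A replicate 1 (0.317) or 2 (0.258), and that of Tap1 without YAP5SA-S94A replicate 2 (0.0538). Without YAP5SA-S94A replicate 1 the interferon list was called lower (camera adjusted p = 0.00373), with 7 genes that fell, as it was without YAP5SA replicate 2 (adjusted p = 0.0438). The number that fell was 2 without YAP5SA replicate 1 or YAP5SA-S94A replicate 2, and the number that rose was 2 without YAP5SA replicate 2 and 0 without YAP5SA-S94A replicate 2.

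The antioxidant and unfolded protein lists had no list call by camera at the reported settings. Of 19 antioxidant NRF2 genes 3 rose and 9 fell (5 and 11 when adjusted over the list alone; camera adjusted p = 0.0692), and the list was called lower without YAP5SA replicate 2 (adjusted p = 0.0438) and with no filter (adjusted p = 0.0387). Heme oxygenase (Hmox1) fell from 276 ± 17.6 to 68.1 ± 9.90 TPM, Srxn1 by 1.07 on the log2 scale and Sod2 by 0.75, while the glutathione transferase gene Gstm1 rose by 1.65. The number that fell was 4 without YAP5SA-S94A replicate 1 and 5 without replicate 2, where 1 rose. Of 23 unfolded protein response genes 3 rose and 7 fell (4 and 7 when adjusted over the list alone; camera adjusted p = 0.27), with 1 that rose without YAP5SA-S94A replicate 1 and 0 without replicate 2. Herpud1, Dnajb9 and Hyou1 fell by 1.16, 1.16 and 0.61, and Ddit3, which overlaps expressed genes on the opposite strand, by 1.41.

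Markers of other cell types moved in part. In the epicardial and mesothelial list 5 of 10 tested genes rose and 0 fell, also when adjusted over the list alone (median 0.51; camera adjusted p = 0.045; adjusted p = 0.399 with an estimated correlation). They included Krt18, Upk3b (20.3 ± 2.93 against 0.577 ± 0.048 TPM), Krt19 (log2 fold change 2.19) and Aldh1a2 (0.91), and the list call was lost without YAP5SA replicate 1 (camera adjusted p = 0.0777) and without YAP5SA replicate 2 (adjusted p = 0.117). Of 26 fibroblast and matrix genes 6 rose and 2 fell (5 and 2 when adjusted over the list alone), with a median of 0.17 and no list call (camera adjusted p = 0.114), though the list was called higher without YAP5SA replicate 2 (adjusted p = 0.0181, 11 genes that rose) and without YAP5SA-S94A replicate 1 (adjusted p = 0.0328), and 4 fell without YAP5SA replicate 1. The median was 0.028 without YAP5SA replicate 1 and 0.086 without YAP5SA-S94A replicate 2. Fibronectin (Fn1) stood at 1109 ± 119 against 388 ± 9.91 TPM, and Mfap5, Lox and Tnc rose by 2.71, 2.26 and 2.16. Of 14 smooth muscle and pericyte genes, 3 of them also in another list, 4 rose and 1 fell (5 and 1 when adjusted over the list alone; camera adjusted p = 0.123), with Mcam at 1.27 and Abcc9, also a potassium channel subunit gene of cardiomyocytes, at −2.77. The list was called higher without YAP5SA replicate 2 (camera adjusted p = 0.0425). Of 13 immune genes 1 rose and 4 fell (1 and 5 when adjusted over the list alone; camera adjusted p = 0.068), and the list was called lower with no filter (adjusted p = 0.0347). The macrophage receptor gene Csf1r rose by 1.40, while Lyz2, C1qa and Cd68 fell by 0.72, 0.68 and 0.60. The limma call of C1qa was lost without YAP5SA-S94A replicate 1 (adjusted p = 0.164) and with no filter (0.0541), and that of Cd68 without YAP5SA-S94A replicate 2 (0.0536). The number of immune genes that fell was 2 without either YAP5SA-S94A library. Of 10 endothelial genes 2 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.86). Kdr fell by 2.22, Fabp4 by 0.74, Tek rose by 1.42, and Flt1 had a log2 fold change of 0.63 whose call was lost without each library in turn (limma adjusted p = 0.072 to 0.275), leaving 1 gene that rose without YAP5SA replicate 1 or either YAP5SA-S94A library. Of 5 Schwann cell and neural genes only Mbp was called (log2 fold change 1.98), also when adjusted over the list alone (camera adjusted p = 0.914), and the list's mean of 0.09 and median of −0.41 differed in sign; without YAP5SA replicate 1, 2 of its genes fell, and without YAP5SA replicate 2 the median was −0.27. Only 2 erythroid genes were tested, too few for a list test, with Slc4a1 at 3.11 ± 0.44 against 4.59 ± 0.36 TPM and Ahsp at 2.30 ± 0.34 against 1.42 ± 0.11.

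Library checks gave the following values. Of 39 cytosolic ribosomal protein genes 7 rose and 0 fell, and 0 were called when adjusted over the list alone in limma, with 5891 of all tested genes at an unadjusted p under 0.05. The list's median was 0.20 (camera adjusted p = 2.68e-04; adjusted p = 0.507 with an estimated correlation), and its call was lost without YAP5SA-S94A replicate 1 (adjusted p = 0.0669) and without replicate 2 (adjusted p = 0.178), where 1 and 0 genes were called, against 16 without YAP5SA replicate 1 and 11 without YAP5SA replicate 2. Rps19, Rpl8, Rpl4 and Rps16 had log2 fold changes of 0.45, 0.49, 0.36 and 0.33, and the call of Rps16 was also lost without YAP5SA replicate 1 (limma adjusted p = 0.0548). Of 12 housekeeping genes 5 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.27), with Actb at 2506 ± 191 against 1195 ± 50.2 TPM, Hprt1 at 1.24, Ywhaz at 0.59 and Ppia at 0.54 on the log2 scale. The sex-linked list held 4 tested genes, too few for a list test, and none was called, with Eif2s3y at 33.5 ± 1.77 against 38.9 ± 0.27 TPM and Kdm5d at 4.16 ± 0.34 against 5.26 ± 0.91. Together 13 of 35 tested lists were called higher and 7 lower by camera with its preset correlation. With an estimated correlation 0 were called, 6 had an unadjusted p under 0.05, and fry's directional test called 18. Camera with an estimated correlation rests on 2 residual degrees of freedom, which left little room for calls over 35 lists. The count of 0 thus does not show that correlation among genes undoes the list calls.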

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

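Leaving out the mitochondrial chromosome, and for the lists median-of-ratios scaling, a pseudocount of 5, no filter and the variance models, were chosen after seeing the data; the other alternatives were set before. No gene called both with the reported settings and in an alternative changed sign. Among alternatives that keep the threshold and all 4 libraries, 3213 (no filter) to 5319 genes were called.

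A stricter threshold lowers the counts by construction. With a log2 fold change of at least 1, 1615 genes were called, 1005 higher and 610 lower. With an adjusted p under 0.01, 2485 were called, 1439 higher and 1046 lower. With a library left out, the genes called lower ranged from 1312 (without YAP5SA-S94A replicate 1) to 2739 (without YAP5SA replicate 1). There the lone library was assumed to vary like those of the other group. Without a YAP5SA-S94A library, the spread came from the YAP5SA pair alone, which was less alike (r = 0.985 against 0.991). A call lost in such a fit can therefore reflect the spread used and not a smaller difference. The cause of the range was not tested.

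With the correlation estimated per list, camera called 0 lists, against 20 with the preset one; 6 had an unadjusted p under 0.05, and fry called 18 in its directional test. Fry's mixed test, which asks whether genes of a list change either way, called 35. These were all the lists tested, the housekeeping list among them (fry mixed adjusted p = 0.00153). Fry does not compare a list with the other genes, as camera does. With 32.9% of all tested genes called, its counts are not comparable with those of camera. In some called lists the estimated correlation lay above the preset 0.01, up to 0.89 for mitochondrially encoded genes. In others it lay below, at −0.0186 for S phase, −0.0036 for fatty acid oxidation and −0.0353 for cholesterol synthesis. The unadjusted camera p of these lists still increased, from 3.48e-08, 9.64e-12 and 9.12e-13 to 0.0224, 0.0158 and 0.0158. A higher correlation thus does not account for the loss of these calls. With an estimated correlation, camera reads its statistic on the 2 residual degrees of freedom, which raises p even where the correlation is low. Fry's directional calls left out the immediate early, cardiac transcription factor, sarcomere turnover and mitochondrially encoded lists that camera called. They added the antioxidant NRF2 list (fry adjusted p = 0.0109) and the housekeeping list (0.0276). Among camera runs at the preset correlation only, list calls were lost in at least 1 setting for 4 lists and gained for 5.

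The replicate block, with the title numbers as pairs, called 5319 genes. The titles and the library numbers disagree, and deviations of libraries with the same title number correlated at 0.101 across genes, which gives no ground for pairing.

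Among the named genes 14 lost a call in at least 1 setting and 2 gained one. Wwtr1, not called in any setting, was the only named gene whose direction reversed: −0.0044 with FPKM, −0.047 without the mitochondrial chromosome, and −0.26 to 0.31 with a library left out. The cause was not tested, and its replicates lay further apart than the groups.

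Read counts per gene were not available here, so counting error of low genes could not be computed. YAP5SA replicate 2 was the shallowest library, at 4.02 gigabases.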

Other observations

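All tests of this part were chosen after the values of the genes concerned, or of members of their lists, had been seen. Genes are not independent replicates in any of them.

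Several genes of skeletal muscle were higher in YAP5SA: Myh3, Myh8, Myh2 (20.4 against 0.055 TPM), Cacna1s (51.7 against 1.86) and Klhl41 (283 against 33.8). A list of 44 skeletal muscle genes without these had 17 tested members, of which 7 were called higher, Myh1 (3.44), Atp2a1 (2.74) and Acta1 (0.97) among them, and 5 lower, among them Klhl40 (−1.46) and Trim72 (−1.28). The list was not called (camera p = 0.551; p = 0.61 with an estimated correlation; p = 0.435 over the 14 genes in no fixed list). Reads of the cardiac myosins assigned to paralogs do not account for the 4 other myosin genes (Myh3, Myh8, Myh2 and Myh1). Such reads would follow the cardiac myosins. In each of 4 pairings of libraries, the median log2 fold change of the 4 lay at least 5.613 above that of the Myh6 and Myh7 sum. Reads shared among the 4 were not tested, so the increases of Myh8, Myh2 and Myh1 may not be separate from that of Myh3. Cells of skeletal muscle in the YAP5SA cultures were tested on 7 transcripts of skeletal muscle, which combine a first set (Acta1, Ckm, Tnnt3, Myh1) with a later one (Tnnc2, Tnni2, Tnnt3, Myl1, Ckm). Of the 7, 2 (Acta1 and Myh1) were higher in both YAP5SA libraries than in both others. Ckm fell from 1023 to 247 TPM and Myl1 from 167 to 102, from levels that would hide a small share of such cells, and Tnnc2, Tnni2 and Tnnt3 reached at most 0.969 TPM in YAP5SA. Such cells and induction of some muscle genes within the cardiomyocytes both stay open.

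Mitosis genes were higher in YAP5SA. More fibroblasts would raise fibroblast genes too, but the median of that list was 0.17, with an upper 95% bootstrap bound of 0.3258 (10000 resamples over genes), while the mitosis list had a median of 1.31. The fibroblast median was 0.028 without YAP5SA replicate 1 and 0.086 without YAP5SA-S94A replicate 2. It was 0.23 without YAP5SA replicate 2 (camera adjusted p = 0.0181) and 0.21 without YAP5SA-S94A replicate 1 (camera adjusted p = 0.0328), where the list was called higher, so the test speaks only against fibroblasts as the whole cause. A difference in depth between libraries is argued against by the 53 mitosis genes called higher without the shallowest library, YAP5SA replicate 2. Which cell type expressed these genes stays open, and mesothelial and some fibroblast genes also rose.

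More sarcomere genes fell (16) than rose (8) in YAP5SA. A lower share of cardiomyocytes would lower sarcomere genes alike, but 8 were called higher. That number was 5 without YAP5SA-S94A replicate 1, 3 without replicate 2 and 4 without a filter, so the test speaks only against a lower share as the whole cause.

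Imprinted genes were noticed among large increases: Peg10 (63.8 against 4.72 TPM), Plagl1 (52.9 against 2.32) and Nnat (124 against 6.17). A list of 25 imprinted genes without these had 19 tested members, of which 9 were called higher, such as Snrpn (1.96), Nap1l5 (1.72) and H19 (1.10), and 2 lower, Mest (−0.77) and Cdkn1c (−0.57). Its median was 0.49 (camera with a preset correlation, p = 0.00217, and p = 6.3e-04 over the 16 genes in no fixed list). With an estimated correlation the list was not called (p = 0.208). Imprinted genes may be part of a fetal program that differs between the forms, which was not tested further.

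Some proteins have a ubiquitous or fetal and a muscle or adult isoform. In 15 of 16 such pairs, chosen by hand after members of several had been seen to fall, the first had the higher log2 fold change, with a median difference of 1.06. Creatine kinase (Ckb 1.46, Ckm −2.06) and enolase (Eno1 0.85, Eno3 −1.73) were among them, and Cox7a2 with Cox7a1 was the exception (−0.38). No test is given, because the pairs were not chosen independently of their values.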
